A study of Homo sapiens with 2 samples.

How the data were processed

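Single-cell RNA was measured with the 10x Genomics 3' assay, version 3.1, in 2 libraries of human inner ear organoids collected on day 40, per the labels' protocols. The organoids were grown from the WA25 human embryonic stem cell line carrying a nuclear tdTomato reporter at SOX2, a transcription factor gene of otic and neural progenitors. Only reporter-positive cells were loaded, after 90 min in Accutase and sorting by flow cytometry. The groups were GelNB-CH, a photo-crosslinked gelatin hydrogel made with 0.1 wt% of a 4-arm thiol crosslinker, and Matrigel, a basement membrane extract, with 1 library per group. The group of each library rests on its title and treatment label. The growth text given for both libraries describes embedding in GelNB-CH on day 11 and an oxidized dextran step at 0.02% on day 15, so no embedding step for the Matrigel library is described in the sources used here.

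The values deposited for each library are counts of unique molecular identifiers (UMIs), whole numbers per gene and cell barcode, filtered to called cells and not normalised, per the file headers and the labels' protocols. The software that made them is Cell Ranger, given as 4.0.0 in the labels' protocols and as 7.1.0 per the file headers, and the submitters' processing notes also name STAR and the GRCh38 (hg38) build. The annotation version is not given in the sources used here. The matrices list 36601 genes and have no separate entry for the reporter transcript. Coordinates were taken from the GENCODE v29 annotation of GRCh38 by Ensembl identifier, which matched 34616 of the listed genes.

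Cells were kept with at least 1000 detected genes and at most 15% of UMIs from mitochondrially encoded genes. Scrublet, run through scanpy 1.11.5 on each library with an expected rate of 0.8% per 1000 barcodes and its automatic threshold, marked 14.2% of GelNB-CH and 6.55% of Matrigel barcodes as doublets, which were removed. Both libraries were clustered together from log counts scaled to 10000 per cell, with 2000 variable genes ranked within each library, 30 principal components, 15 neighbours and Leiden clustering at resolution 1.0. The software was Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, igraph 0.11.9, and edgeR 4.0.16 under R 4.3.3.

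The 22 clusters were named from 19 marker lists written before the data were examined. A marker counted for a cluster when at least 10% of its cells had a UMI of it and its CPM (counts scaled to the same total) were at least 2-fold above the median cluster. A name needed at least 3 such markers and at least a share of 0.3 of its list, and none was given where the 10 leading genes held more markers of another type. These limits and the scoring were set after the data were seen. Lists were first ranked by the number of markers, which left the cartilage and melanocyte clusters unnamed, and then by a binomial score, which is the rule used. No cluster was named hair cell-like, and hair cell-like cells were therefore taken as cells with a UMI of at least 8 of the 16 hair cell markers, a definition also set after the data were seen.

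The CPM values were computed here from the deposited counts, summed over all kept cells of a library or over the cells of a class. Gene ratios have exact 95% intervals from the conditional binomial distribution, and shares have exact Clopper-Pearson 95% intervals. All intervals cover counting error only. With 1 library per group there is no replicate, so no test was made, no p-value is given, and each difference holds for these 2 libraries. Genes were counted as apart when the larger CPM was at least 10 and the ratio at least 2, which describes the libraries and is not a call of changed genes. The 31 gene lists and 19 marker lists were fixed before the data were examined. For each list the median of log2 ratios of CPM plus 1 was placed among 10000 random lists of the same size matched on expression in 20 bins, and its percentile describes these libraries. For shares of cells with a UMI, each cell was also thinned to 5000 UMIs, which left out 1939 GelNB-CH and 418 Matrigel cells with fewer.

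The genes named were fixed by rule: the 12 largest ratios in each direction over all cells, and the 10 largest within otic epithelium-like cells, among genes with a larger CPM of at least 20 and an interval excluding 2-fold, with Y-linked, mitochondrial, ribosomal and clone-named genes left out. From each list, the 2 members with the largest and the 2 with the smallest ratio, among those with a CPM of at least 5, could serve as examples. SOX2 is always named. Genes named within hair cell-like cells, by kind of cell, or as apart in many kinds were chosen after their values were seen.

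The alternatives set before the data were read changed the cell filter, doublet removal, clustering, class assignment, depth, scaling, expression minimum and pseudocount. Comparisons of cells of like depth (8000 to 16000 UMIs), of otic clusters weighted to the same make-up, and of otic cells without cluster 6 or cluster 10, and SOX2 by otic cluster, were chosen after seeing the data, as were the alternatives for classes other than hair cell and otic. The gene comparison was tested on simulated counts for each of its 2 uses, drawn from the libraries' own means with 200 genes changed. Over all cells (10284 genes), 0 of 50 genes changed 1.5-fold and 50 of 50 changed 2.5-fold passed the 2-fold rule, and the intervals held the true ratio for 95.0% of genes. In otic cells (10183 genes), the recovery was likewise 0 of 50 and 50 of 50. No unchanged gene passed in either, out of 10084 and 9983. The simulated counts varied by counting error only, so the check does not cover variation between libraries, and at this depth these outcomes were nearly fixed.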

Results

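Sorted SOX2 reporter-positive cells from day 40 human inner ear organoids were profiled in 1 GelNB-CH library and 1 Matrigel library. GelNB-CH is a chemically defined hydrogel of modified gelatin, and Matrigel is a tumour-derived mixture rich in laminin and collagen IV. The GelNB-CH library held 21743 barcodes and 247006223 UMIs, and the Matrigel library 10912 barcodes and 178672097 UMIs. After filtering, 18253 cells (83.9%) and 9800 cells (89.8%) were kept, with medians of 8558 and 14001.5 UMIs and of 3111 and 4219 genes per cell. There were no replicates, so the values below compare the libraries only.

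The title of the series asks whether the defined hydrogel supports hair cell differentiation. Cells carrying a hair cell programme were present in both libraries and rare in both. In GelNB-CH, 16 of 18253 cells had a UMI of at least 8 of 16 hair cell markers, a share of 0.0877% (95% interval 0.0501% to 0.142%), and in Matrigel 12 of 9800 cells did, a share of 0.122% (0.0633% to 0.214%). These intervals overlap widely. Marker scores without clustering gave 1.36% and 1.28%, but they placed every cell in its highest-scoring type with no minimum. Those shares therefore hold many cells with few hair cell markers and are not a like estimate. Of the cells with at least 8 markers, 14 in GelNB-CH and 11 in Matrigel lay in cluster 9, an unnamed epithelial cluster with 13 otic markers and keratin genes. Few other cells came near this limit in GelNB-CH, where 1 cell had 6 or 7 markers and 3 had 5, while in Matrigel 3 cells had 6 or 7 and 20 had 5. The hair cell-like cells had medians of 11136 and 21239 UMIs, so the deeper Matrigel cells had more chance to reach 8 markers.

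Genes of the hair bundle that were not used to find these cells had similar levels in both libraries. MYO15A, a motor that lengthens stereocilia, stood at 394 CPM in GelNB-CH and 405 CPM in Matrigel hair cell-like cells (interval of the ratio 0.747 to 1.27). GRXCR1, which shapes stereocilia, stood at 465 and 423 CPM (ratio 1.10, 0.857 to 1.41), and PTPRQ, a phosphatase of the bundle, at 631 and 557 CPM (ratio 1.13, 0.915 to 1.40). In the otic epithelium-like cells outside this set MYO15A was at 1.13 and 1.46 CPM and GRXCR1 at 0.026 and 0.040 CPM, far below. Transcription factors were also present: HES6 was at 2857 and 2214 CPM (ratio 1.29, 1.16 to 1.43), and BARHL1 at 70.6 and 43.8 CPM (ratio 1.61, 0.773 to 3.36). CABP2, a calcium sensor of the hair cell synapse, was at 108 and 59.3 CPM (ratio 1.82, 0.999 to 3.34).

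Among genes listed for vestibular hair cells, SKOR1 was higher in GelNB-CH hair cell-like cells by 5.37-fold (1.38 to 30.4, 10 and 3 counts) and ZBBX by 3.76-fold (1.36 to 11.9, 14 and 6 counts). VEPH1 of the same list had a ratio of 0.322 (0.0600 to 1.14). Of genes listed for cochlear hair cells, TMPRSS3 had a ratio of 2.23 (1.03 to 4.95) and GATA3 rested on 3 and 1 counts. TMC1, a mechanotransduction channel gene and one of the 16 markers, had 0 counts among 240846 UMIs in GelNB-CH and 2 among 388005 in Matrigel. KCNA10, SLC17A8 and FSCN2 had 0 counts in both.

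**Figure D1:**
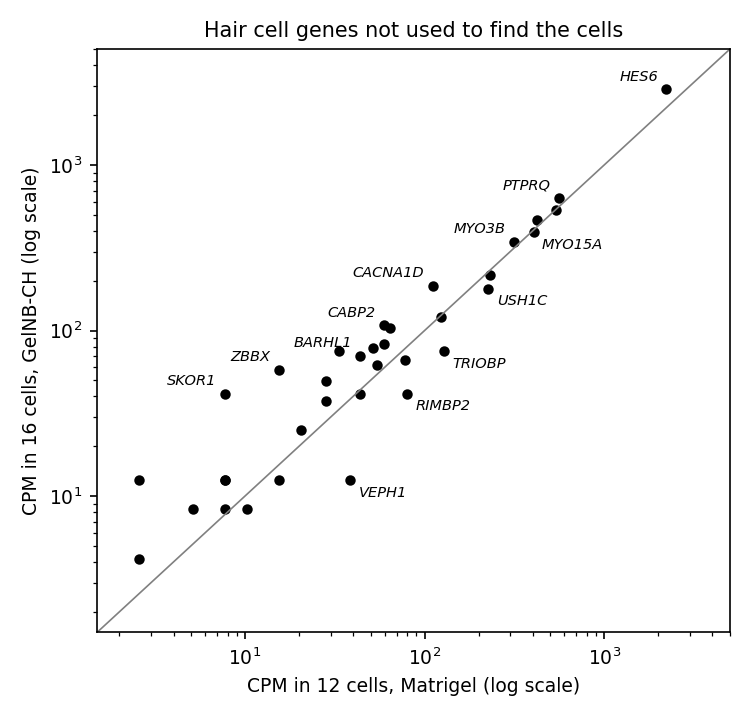
Levels of hair cell genes outside the marker list, as CPM on log axes, in the 12 Matrigel cells (horizontal) and the 16 GelNB-CH cells (vertical) with at least 8 of 16 hair cell markers; each point is a gene with counts in both libraries and the line marks equal levels. HES6, PTPRQ and MYO15A lie near the line, and SKOR1 and ZBBX lie above it.

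Otic epithelium-like cells made up more of the GelNB-CH library than of the Matrigel library. Their share was 36.7% (36.0% to 37.4%) in GelNB-CH and 27.3% (26.4% to 28.2%) in Matrigel, a difference of 9.44 percentage points. Schwann or satellite glia-like cells, the support cells of peripheral nerve, went the other way. They were 3.44% (3.18% to 3.71%) in GelNB-CH and 16.7% in Matrigel, 4.86-fold more. This class leaves out cluster 14, unnamed though it had all 10 markers, and the fold was 3.65 at resolution 0.5. With each library clustered on its own the shares were 6.97% and 17.4%. Clusters were then named per library, so the class may not hold like clusters in both. Central nervous system progenitor-like cells were 2.98-fold more frequent in GelNB-CH (4.02% and 1.35%), but with each library clustered on its own their shares were 4.71% and 4.45%, and at resolution 2.0 no cluster had this name. Cartilage-like cells were 1.79-fold more frequent (8.58% and 4.79%), a direction that reversed with each library clustered on its own. Mesenchyme-like cells were near 27.9% and 26.0%, and neuron-like cells near 6.61% and 7.83%. Melanocyte-like cells made up 0.394% and 0.0306%, and 72 of their 75 cells were in GelNB-CH, so that cluster may reflect its library.

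Of the clusters, 4 had no name and held 12.3% of GelNB-CH cells. Cluster 14, with all 10 Schwann or satellite glia markers but led by GPR17 of the oligodendrocyte list, was 3.54% of GelNB-CH and 8.74% of Matrigel cells, and cluster 2, a mesenchyme-related cluster with PAX3, was 5.73% and 4.24%. Cluster 9 was 2.84% and 2.42%, and cluster 21, with 10 neuron markers, 0.192% and 0.633%. The shares describe cells that passed the SOX2 reporter gate, whose position can set them, and the cell filter, which 424 GelNB-CH and 413 Matrigel barcodes failed, with depth differing as given above. With each class taken from marker scores without clustering, the otic difference was 0.923 points.

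**Figure D2:**
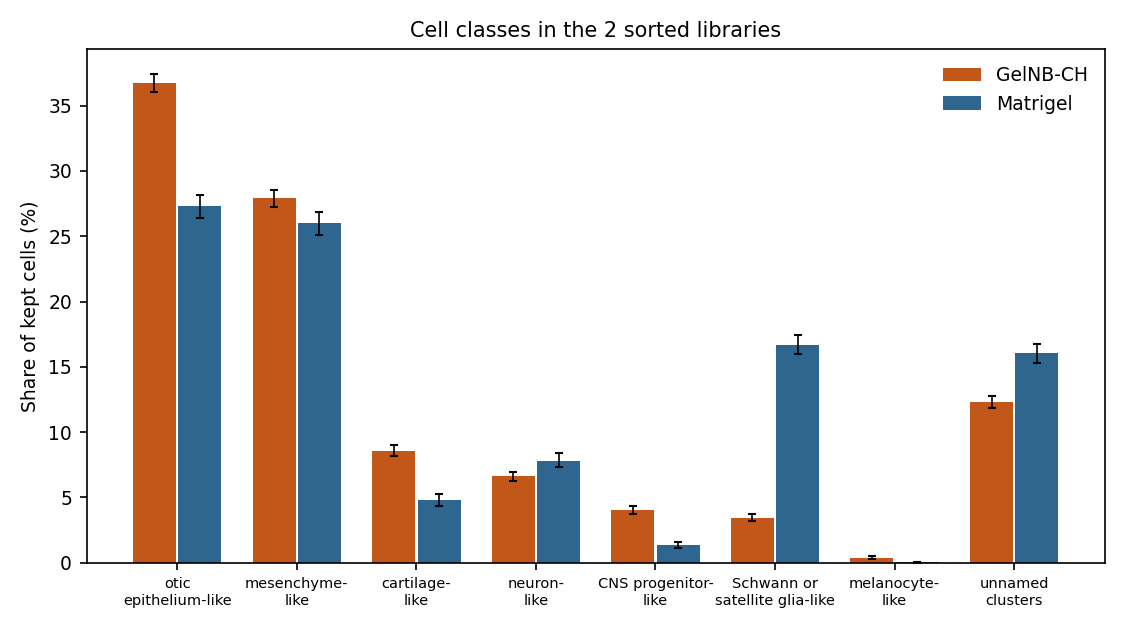
Share of kept cells (%) in each named class and in unnamed clusters, in GelNB-CH (orange) and Matrigel (blue); bars are shares of 1 library each and error bars are exact 95% binomial intervals. Otic epithelium-like cells were 36.7% and 27.3%, and Schwann or satellite glia-like cells 3.44% and 16.7%.

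SOX2 (ENSG00000181449, GRCh38 chromosome 3, 181711924 to 181714436), whose reporter defined the sort, had close levels over all kept cells, at 16.8 CPM in GelNB-CH (16.2 to 17.4) and 17.9 CPM in Matrigel (17.2 to 18.6). It was highest in central nervous system progenitor-like cells, at 116 and 110 CPM. In otic epithelium-like cells it was 1.68-fold higher in Matrigel (1.54 to 1.84), at 12.4 and 20.8 CPM, and 1.48-fold with the otic clusters weighted to the same make-up. The fold ran from 1.04 in cluster 12 to 2.65 in cluster 6. A SOX2 UMI was found in 11.8% of GelNB-CH and 18.1% of Matrigel cells, and in 7.30% and 7.72% once cells were thinned to 5000 UMIs. Cartilage-like cells gave 1.76% and 1.09% after thinning, with medians of 9318 and 14534 UMIs before it, and mesenchyme-like cells 2.64% and 2.89%. OC90, an otoconial matrix gene, was at 1859 and 1029 CPM over all cells.

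Over all kept cells, genes of Schwann and satellite glia were among the largest differences. Higher in Matrigel were ARHGAP15, a GTPase regulator, at 43.9 against 3.99 CPM, GFRA3, an artemin co-receptor, by 6.51-fold (6.06 to 6.99), INSC by 5.88-fold (5.55 to 6.22), FOXD3, a neural crest transcription factor, by 4.99-fold (4.64 to 5.38), its antisense neighbour FOXD3-AS1 by 4.81-fold (4.54 to 5.10), LGI4, a Schwann cell signal, by 4.59-fold (4.29 to 4.90) and CDH19 by 4.56-fold (4.43 to 4.71). NPR3, a natriuretic peptide clearance receptor, was 4.32-fold (4.17 to 4.47), ITGA4 4.22-fold (4.04 to 4.40) and PRSS12 4.14-fold (3.91 to 4.38) higher there. OLFML2A and COL19A1 also met the rule, and each leads a glial cluster. GFRA3, FOXD3 and CDH19 are themselves markers of that class, so their folds are not separate from its 4.86-fold share.

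Higher in GelNB-CH were LRP2, an endocytic receptor of epithelia, by 3.29-fold (3.22 to 3.37), CSMD1 by 3.42-fold (3.29 to 3.55), SPX, which encodes the peptide spexin, by 3.39-fold (3.30 to 3.48), GPR12 by 3.29-fold (3.06 to 3.54), the long non-coding RNA SILC1 by 3.21-fold (2.99 to 3.45), ANOS1, the anosmin gene, by 3.01-fold (2.83 to 3.20) and PART1 by 2.64-fold (2.49 to 2.81). CSMD1 (ENSG00000183117, chromosome 8, 2935353 to 4994972) was higher in each of the 5 kinds of cell that expressed it. Of the others, SPX was higher in 2 of 2 such kinds, LRP2 in 3 of 4, SILC1 in 2 of 3 and ANOS1 in 2 of 4. GPR12 and PART1 were each expressed in 1 kind only and were higher there. CASC17, CXCL14, HIST1H3D, NPW and OTX2 also met the rule, and each is a leading gene of a cluster. CASC17 and OTX2 lead cluster 6 and NPW leads cluster 3, so their ratios are not fully separate from those clusters' sizes. These clusters were 3.50-fold and 5.60-fold more frequent in GelNB-CH. CXCL14 (3.36-fold) and HIST1H3D (3.28-fold) lead clusters 9 and 15, whose sizes, 1.18-fold and 1.30-fold larger there, fall short of these ratios. HIST1H3D was at least 2-fold higher in 4 of the 4 kinds that expressed it.

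Of 10568 genes compared over all cells, 75 were at least 2-fold higher in GelNB-CH and 147 in Matrigel. Much of this came from the mix of cells: with both libraries weighted to the same make-up of classes, 104 genes were that far apart, 55 higher in GelNB-CH and 49 in Matrigel, and 84 of them were among the 222 found without weighting. The balance also moved with scaling, to 102 and 124 with edgeR's TMM factors, which differed by -0.09 on the log2 scale.

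Within otic epithelium-like cells, most of the genes named differed in the same direction in every otic cluster that expressed them. GJC3, a connexin gene (ENSG00000176402, chromosome 7, 99923269 to 99929620), was 3.64-fold higher in GelNB-CH (3.32 to 4.00) and at least 2-fold higher in 5 of 5 clusters, and ANOS1 was 4.72-fold higher (4.28 to 5.21) and at least 2-fold higher in 4 of 4. SILC1 was 3.41-fold higher (3.13 to 3.73), COL21A1, a fibril-associated collagen, 3.35-fold (3.01 to 3.73), GRIA4, an AMPA receptor subunit, 3.49-fold (3.20 to 3.82), CSMD1 3.23-fold (3.07 to 3.40) and DPP10 3.22-fold (3.13 to 3.32). GRIA4 was higher in 3 of the 4 clusters that expressed it, and DPP10 in 4 of 5. ATP13A5, CCDC195 and CASC17 had larger ratios, but they lead cluster 6, which held 2611 of the 6706 GelNB-CH otic cells and 400 of the 2675 Matrigel otic cells. Make-up is not the whole source of these ratios. Of the clusters that expressed each gene, ATP13A5 was at least 2-fold higher in 3 of 3, CCDC195 in 2 of 3 and CASC17 in 4 of 5.

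Higher in Matrigel otic cells were genes of varied function. PURPL, a long non-coding RNA of the p53 pathway, was 4.81-fold higher (4.27 to 5.43), ATF5, a stress-response transcription factor (ENSG00000169136, chromosome 19, 49928702 to 49933935), 3.89-fold (3.72 to 4.07), NDUFA4L2, a hypoxia-induced mitochondrial gene, 3.36-fold (3.16 to 3.57) and STC2, a secreted stress-response glycoprotein, 3.34-fold (3.01 to 3.71). SPON1 was 3.95-fold (3.54 to 4.42), the catenin gene CTNNA2 3.61-fold (3.48 to 3.74), NPR3 3.12-fold (2.86 to 3.41) and PDZRN4 3.12-fold (3.00 to 3.23) higher. NPR3 was at least 2-fold higher in 5 of 5 clusters, and ATF5 and NDUFA4L2 in 4 of 5. WIF1 also met the rule and leads cluster 5.

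Of 10468 genes compared in otic epithelium-like cells, 115 were at least 2-fold higher in GelNB-CH and 81 in Matrigel. The class was split differently in the libraries: besides cluster 6, cluster 12 held 1624 and 511 cells, cluster 5 held 1210 and 647, cluster 10 held 645 and 906, and cycling cluster 11 held 616 and 211, in GelNB-CH and Matrigel. With these clusters weighted to the same make-up, the counts were 55 and 61.

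Genes of the hypoxia and glycolysis list were lower in GelNB-CH throughout the otic epithelium. All 17 were lower, with a median log2 ratio of -0.91, at percentile 0.00 of matched random lists, and the medians in the 5 otic clusters ran from -1.10 to -0.75. SLC2A1, the main glucose importer, was 2.86-fold lower in GelNB-CH otic cells, at 28.5 against 81.4 CPM, and CA9, a carbonic anhydrase induced by low oxygen, was at 3.07 against 10.0 CPM. The smallest gaps were in HK2, a hexokinase, at 9.45 against 13.7 CPM, and ANKRD37, at 7.41 against 10.5 CPM. After thinning to 5000 UMIs, an otic cell had a median of 5 UMIs from the list in GelNB-CH (10th to 90th percentile 2 to 15) and 11 in Matrigel (3 to 25). Over all cells the median was -0.57, and it was -0.99 in central nervous system progenitor-like, -0.69 in neuron cluster 8, -0.61 in mesenchyme-like, -0.48 in neuron cluster 7 and -0.44 in cartilage-like cells. In Schwann or satellite glia-like cells it was -0.03, with 8 members higher and 9 lower.

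Heat shock genes went the other way. Their median was 0.60 over all cells and 0.41 in otic cells, both at percentile 100, with 10 of 10 and 9 of 10 members higher in GelNB-CH. HSPA1A, the inducible HSP70 chaperone, was at 184 against 73.6 CPM over all cells and 2.60-fold higher in otic cells (2.51 to 2.70), and HSPA1B was 1.81-fold higher in both. HSPD1, a mitochondrial chaperone, was 1.19-fold higher over all cells and 1.19-fold lower in otic cells. The median was largest in neuron cluster 8 (1.06) and central nervous system progenitor-like cells (1.02), and smallest in mesenchyme-like and otic cells (0.41 each). Mitochondrially encoded transcripts were higher in GelNB-CH otic cells, with a median of 0.43 and 9 of 10 members higher, among them MT-CO2 by 1.78-fold and MT-ATP6 by 1.73-fold, and their median over all cells was 0.20.

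**Figure D3:**
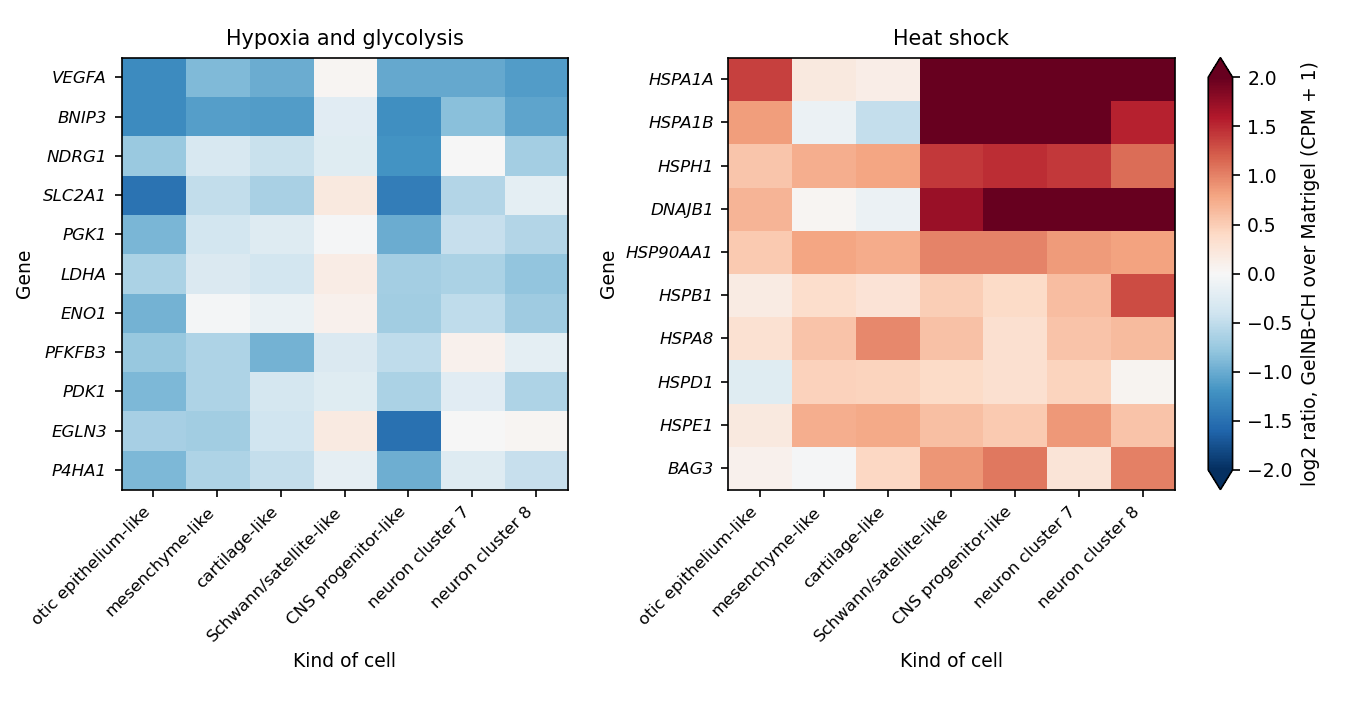
log2 ratios of CPM plus 1, GelNB-CH over Matrigel, for members of the hypoxia and glycolysis list (left) and the heat shock list (right) that were measured in the comparison by kind of cell; columns are kinds of cell, blue is lower and red higher in GelNB-CH, and colours saturate at 2. The hypoxia medians ran from -0.99 to -0.03 and the heat shock medians from 0.41 to 1.06.

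Unfolded protein response genes had a median of -0.44 in otic cells and -0.04 over all cells. TRIB3 and CHAC1, targets of ATF4, were 4.72-fold and 3.34-fold higher in Matrigel otic cells, while SDF2L1 and HSPA5, chaperones of the endoplasmic reticulum, were 1.65-fold and 1.16-fold higher in GelNB-CH. Immediate early genes had medians of -0.40 in otic cells and -0.23 over all cells, with ZFP36 1.78-fold and ATF3 1.55-fold higher in Matrigel otic cells. Between otic cells of like depth, the unfolded protein response median was 0.03 and the immediate early median 0.35, so neither direction held there. Those cells were not matched on cluster, and their cell cycle median was 0.84 against 0.03 in all otic cells. Depth is thus not told apart from the mix of cells. With otic clusters at the same make-up the medians were -0.37 and -0.40. By otic cluster, the immediate early median was 0.30 in cluster 6 and between -0.73 and -0.38 in clusters 5, 10, 11 and 12.

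Extracellular matrix and adhesion lists leaned to Matrigel over all cells. Basement membrane genes had a median of -0.47, with 14 of 16 lower in GelNB-CH, interstitial matrix genes -0.31 and integrins and focal adhesion genes -0.26. With both libraries weighted to the same make-up of classes these were smaller, at -0.20, -0.16 and -0.16. COL18A1 was 2.04-fold higher in Matrigel, the nidogen NID1 1.99-fold, COL5A2 2.30-fold and the metalloprotease inhibitor TIMP3 2.59-fold. ITGA1, the lowest integrin, leads glial cluster 14. In otic cells the basement membrane median was -0.25, while interstitial matrix and integrin medians were -0.00, and POSTN and TNC were 2.74-fold and 2.31-fold higher in GelNB-CH. POSTN stood at 18.6 and 6.77 CPM in GelNB-CH and Matrigel otic cells, against 256 and 179 CPM in mesenchyme-like cells. RNA carried over from mesenchyme-like cells may add to its ratio, which was not tested. Matrix remodelling genes had medians of -0.04 and 0.12, and actomyosin genes -0.04 and -0.05, over all and otic cells. Between cells of like depth the actomyosin medians were 0.09 and 0.31, so their direction did not hold. YAP-TAZ targets had medians of -0.11 and -0.29, with 10 of 12 lower in GelNB-CH otic cells, but between cells of like depth these were 0.05 and -0.10.

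Among signalling lists, BMP and TGF-beta, FGF-ERK and WNT targets lay outside the 95% range of matched random lists over all cells, the latter pair at percentiles 1.11 and 99.4. BMP and TGF-beta targets had medians of -0.24 over all and -0.30 in otic cells, where ID4 was 1.58-fold higher in Matrigel, and FGF-ERK targets -0.27 and -0.21, with SPRY1 2.48-fold higher in Matrigel otic cells. The medians were -0.14 and -0.10 for the NOTCH pathway, 0.14 and -0.06 for WNT targets, and -0.07 and -0.22 for hedgehog targets. Between cells of like depth the NOTCH pathway medians were -0.02 over all and 0.19 in otic cells. Cholesterol synthesis genes had medians of 0.11 and 0.19, p53 targets -0.11 and -0.17, interferon response genes -0.28 and 0.01, and cell cycle genes -0.13 and 0.03. Cytosolic ribosomal protein genes had medians of 0.14 and 0.09, and nuclear long non-coding RNAs -0.13 and -0.22. HOX genes had medians of 0.00 and 0.05. Forebrain and midbrain genes had medians of 0.44 and 0.16. The transcription factors OTX1 and SIX3, both under 10 CPM, were 3.97-fold and 3.30-fold higher in GelNB-CH over all cells. OTX2 of this list, at 21.0 against 7.33 CPM, leads otic cluster 6. By otic cluster the median of this list ran from -0.24 in cluster 5 to 0.77 in cluster 11. In central nervous system progenitor-like cells it was -0.16, with 3 members higher and 5 lower in GelNB-CH.

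**Figure D4:**
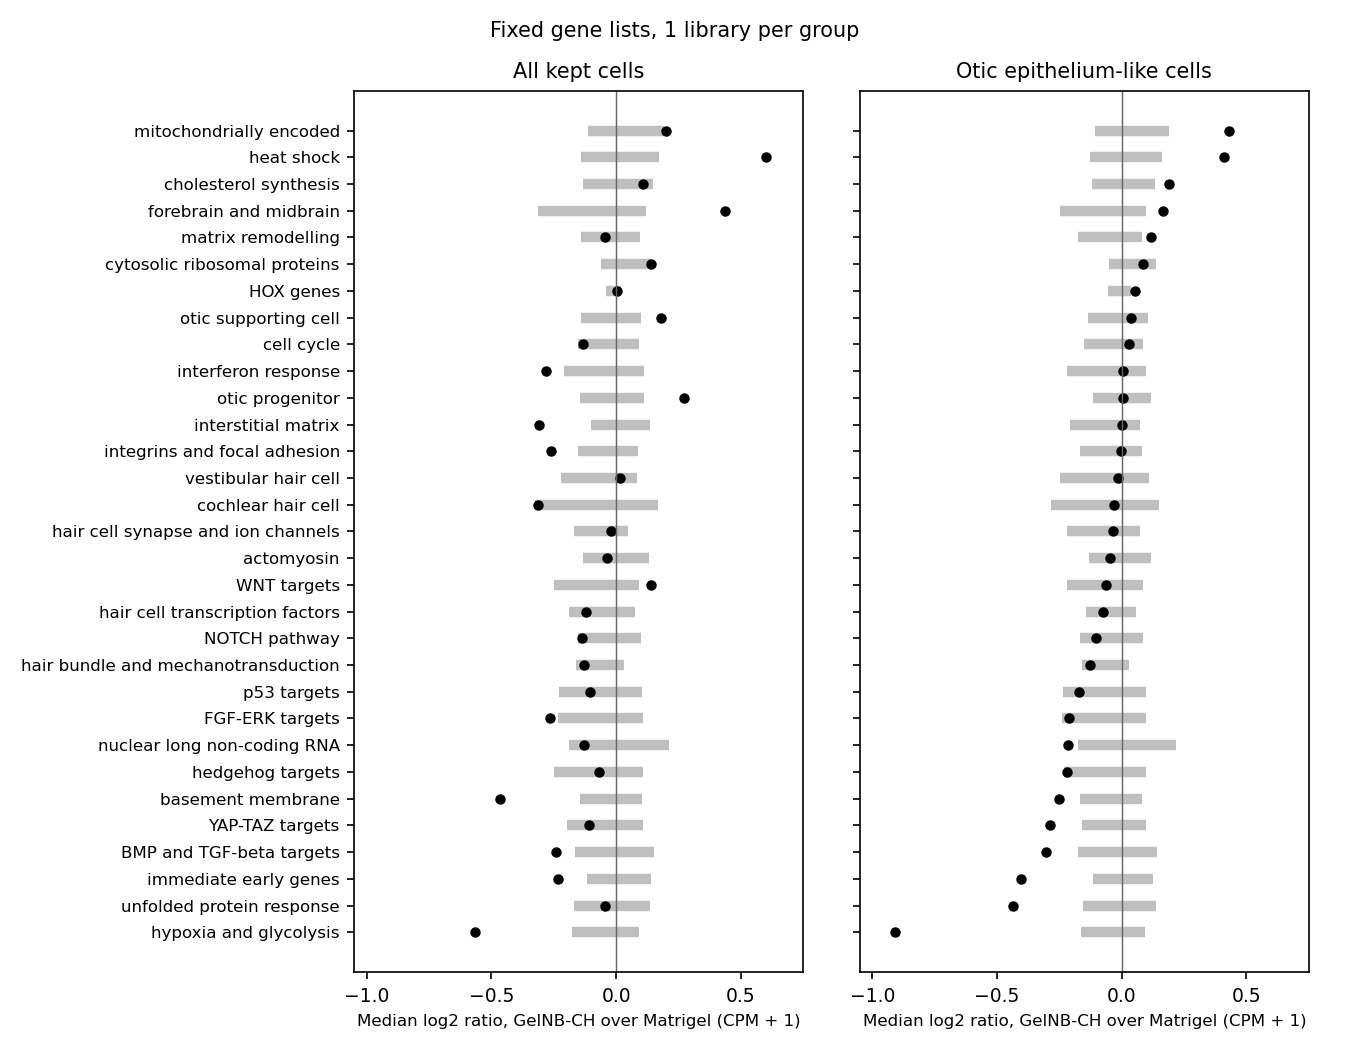
Median log2 ratio of CPM plus 1, GelNB-CH over Matrigel, of 31 fixed gene lists over all kept cells (left) and in otic epithelium-like cells (right); points are list medians and grey bars hold 95% of matched random lists. Hypoxia and glycolysis lies lowest (-0.57 and -0.91), and heat shock lies at 0.60 and 0.41.

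Lists of otic identity were higher in GelNB-CH over all cells and near 0 inside the otic class. Otic epithelium markers had a median of 0.23 over all cells and 0.01 in otic cells, otic progenitor genes 0.27 and 0.01, and otic supporting cell genes 0.18 and 0.04. The supporting cell median ran from -0.25 in otic cluster 5 to 0.26 in cluster 12. It was 0.12 with the otic clusters weighted to the same make-up. OTOGL, an inner ear glycoprotein, was 1.90-fold higher in GelNB-CH over all cells and 1.53-fold in otic cells, while SLITRK6 was 1.95-fold and 1.74-fold higher in Matrigel. Hair cell lists had medians over all cells of -0.12 for transcription factors, -0.13 for bundle and mechanotransduction, -0.02 for synapse and ion channels, 0.02 for vestibular and -0.31 for cochlear genes, and -0.16 for hair cell markers. In otic cells these were between -0.13 and -0.01, but the clusters differed: transcription factor and bundle medians were 0.44 and 0.34 in cluster 11, and -0.33 and -0.32 in cluster 10. Cluster 11 held 2 hair cell-like cells, both from GelNB-CH, and cluster 10 held 1, from Matrigel. Between otic cells of like depth the transcription factor median was 0.21.

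Among markers of other cell types over all cells, medians were -1.66 for Schwann or satellite glia, with 10 of 10 lower in GelNB-CH, 0.42 for cartilage, 0.67 for melanocyte, 0.19 for central nervous system progenitor, -0.10 for neuron and -0.06 for mesenchyme markers. Types without a cluster of their own had medians of 0.92 for surface epidermis, whose largest ratio, in KRT5, belongs to a leading gene of cluster 9, -0.68 for Merkel cell, 0.47 for muscle, 0.27 for choroid plexus or roof plate, 0.21 for motile ciliated cell and -0.27 for oligodendrocyte lineage markers. Endothelium (-0.04), retina (-0.01), olfactory or respiratory epithelium (-0.01), pluripotent cell (-0.04) and immune or blood cell markers (-0.03) were near 0.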

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

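None of the differences below was tested, since each group had 1 library, and the look at cells of like depth and at removed doublets was chosen after the results were seen. Hair cell-like cells also occurred among the cells removed as doublets, which the main comparisons leave out: 7 in GelNB-CH and 1 in Matrigel had at least 8 of the 16 markers. With these counted, the libraries held 23 of 21319 and 13 of 10499 such cells, 0.108% and 0.124%.

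Some lists and genes lay on opposite sides in different kinds of cell, and whether the kinds differ was not tested. The unfolded protein response median was -0.44 in otic epithelium-like cells and 0.17 in mesenchyme-like cells, but 0.04 and 0.02 in otic clusters 5 and 6 and 0.03 between otic cells of like depth. Cholesterol synthesis genes had a median of 0.19 in otic cells, with 11 of 12 higher in GelNB-CH, but of -0.16 and -0.10 in otic clusters 5 and 10 and 0.10 with the otic clusters at the same make-up, and of -0.54 in mesenchyme-like cells, with 12 of 12 lower. Among them HMGCS1, an early enzyme of the pathway, stood at 289 against 225 CPM in otic cells and 206 against 294 CPM in mesenchyme-like cells.

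The neuron clusters also went opposite ways, untested. Cluster 7, led by LHX9, SLC17A6 and MYT1L, took 4.65% of GelNB-CH and 1.28% of Matrigel cells, a ratio of 3.64, and cluster 8, led by NEUROD1 and PPP1R17, took 1.97% and 6.55%, a ratio of 0.3002. SOX2 had a CPM ratio of GelNB-CH to Matrigel of 0.595 in otic epithelium-like cells and 1.54 in Schwann or satellite glia-like cells, a difference that was not tested either.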

How the results depend on the processing

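The planned hair cell gene counts could not be made, since each library held fewer than 30 hair cell-like cells. No paired analysis was possible because each group had 1 library, so the shared replicate number 1 pairs nothing. The otic share difference (9.44 points) kept its direction under all 9 planned settings and was 3.64 with no doublet calls removed, 11.7 at resolution 2.0, 7.01 with each library clustered on its own, 0.923 with classes from marker scores and 10.7 with thinned cells. By marker scores, hair cell-like shares were 1.36% and 1.28%, 0.0832 points apart, so their size depends on the definition. Neuron-like shares reversed by marker scores, to 0.715 points, and cartilage-like shares reversed with each library clustered on its own, to -3.16 points, while the looser filter gave no cartilage cluster, and the cause was not tested. A minimum of 1 CPM, which compares more genes, gave 247 genes higher in GelNB-CH and 539 in Matrigel over all cells, and 282 and 499 in otic cells. A minimum of 50 CPM, which compares fewer, gave 19 and 48, and 32 and 17. Weighting to the same make-up of classes left 104 genes over all cells, but differences in the mix of clusters within a class remain in it. The same weighting for otic clusters left 55 genes higher in GelNB-CH in otic cells. Other scalings, cell filters, thinning, doublet settings and the interval rule gave between 69 and 102 genes higher in GelNB-CH over all cells. Of the list medians in cells of like depth, 43 stayed close and 17 moved, some across 0, as the cell cycle list did from -0.13 to 1.15 over all cells. Immediate early and unfolded protein response genes in otic cells reversed, to 0.35 and 0.0281. The cause was not tested. Cells of 8000 to 16000 UMIs are deep for GelNB-CH and ordinary for Matrigel, so they are not the same part of each library. Median-of-ratios scaling left all 100 list medians close, a pseudocount of 5 moved 5, such as surface epidermis from 0.92 to 0.45, and a member minimum of 5 CPM moved 17, such as forebrain and midbrain from 0.44 to 1.35.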

Other observations

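The tests of cluster make-up and depth for the hypoxia genes, all 3 tests of the Schwann or satellite glia share and the free RNA test on part of the like-ratio genes were chosen only after the results were seen, and genes named here were chosen after their values were seen. WNT target genes, with a median log2 ratio of 0.14 over all cells, were higher in GelNB-CH in Schwann or satellite glia-like cells, with a median of 0.80 and 9 of 10 members higher, and in neuron cluster 8, with a median of 0.58. In the same glia-like cells melanocyte markers had a median of 1.14, cartilage markers 0.60 and neuron markers 0.31, and Schwann or satellite glia markers -0.31. LEF1, a transcription factor of the pathway, stood at 74.4 CPM in GelNB-CH and 35.6 CPM in Matrigel glia-like cells, and at 49.5 against 13.4 CPM in neuron cluster 7. TCF7, its relative, was lower in the same glia-like cells, at 8.66 against 15.3 CPM. YAP-TAZ targets had medians of -0.53 in mesenchyme-like and -0.48 in cartilage-like cells but 0.63 and 0.44 in neuron clusters 7 and 8. CCN2, a matricellular YAP target, was at 135 against 288 CPM in mesenchyme-like cells.

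Muscle markers stood out in the neuron clusters, with medians of 2.58 in cluster 7 and 1.77 in cluster 8 and 7 of 7 members higher in GelNB-CH in each. Schwann or satellite glia markers lay the other way in the same cells, with medians of -2.10 and -0.54. Cluster 7 held 848 GelNB-CH but only 125 Matrigel cells, and cluster 8 held 359 and 642. In cluster 8, ACTC1, cardiac actin, was at 90.7 against 18.5 CPM and TTN, the titin gene, at 22.8 against 8.21 CPM. TTN is also a leading gene of epithelial cluster 9, and no cluster was named muscle. Whether mixed cells or free RNA lie behind the muscle and glial markers in these clusters was not tested. The NOTCH effector HES5 was at 516 against 220 CPM in cluster 7, while the NOTCH pathway median there was 0.21. The number of genes at least 2-fold higher in GelNB-CH and in Matrigel was 60 and 52 in mesenchyme-like, 58 and 117 in cartilage-like, 106 and 146 in Schwann or satellite glia-like and 167 and 277 in central nervous system progenitor-like cells, the last with 132 cells in Matrigel. Neuron clusters 7 and 8 had 160 and 235, and 105 and 120.

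The lower hypoxia and glycolysis genes in GelNB-CH otic cells were weighed against 3 technical explanations. Weighting the 5 otic clusters to the same make-up gave a list median of -0.92, and otic cells of like depth gave -0.91, both close to the reported -0.91 and against make-up or depth as the whole source. Free RNA at the level of OC90 in mesenchyme-like cells could supply 3.25% of the gap of the median member. That level, 3.05% in GelNB-CH and 1.98% in Matrigel of the level over all cells, is not an upper bound. Of mesenchyme genes in otic cells, COL1A2 stood at 5.71% and 4.17%, and POSTN at 16.4% and 3.88%. A larger part from free RNA is therefore not excluded. The matrix itself, the size of the organoids and the handling of each culture stay open and untested, since each group had 1 library.

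A few genes lay apart by a like ratio in nearly every kind of cell. RPS10, a ribosomal protein gene (chromosome 6, 34417454 to 34426125), was 2.15-fold to 2.69-fold higher in GelNB-CH in 7 of 7 kinds, and PHF5A, a splicing factor gene, 1.84-fold to 2.99-fold, while DUOX1 was 2.38-fold to 2.87-fold, FKBP2 1.96-fold to 3.32-fold, AC138123.1 2.09-fold to 5.14-fold and AC006213.2 2.05-fold to 3.20-fold higher in Matrigel. The lowest level of these genes in a kind of cell was 37.9% of that over all cells, in AC138123.1. For RPS10 it was 58.4%, against 3.05% for OC90 in GelNB-CH mesenchyme-like cells. The minimum of 10 CPM allowed RPS10 a level down to 2.08%, so its level argues against free RNA for that gene. The lowest level allowed was 12.9% for AC138123.1 and 23.7% for PHF5A, and higher still for the other 3. A level like that of OC90 could not occur in them, so free RNA stays open for all but RPS10. Overlap with another counted gene on the same strand was found for 33.3% of the 6 genes (RPS10 with RPS10-NUDT3, AC006213.2 with ZNF404), against 13.4% of all genes compared, and with so few genes overlap cannot be told apart from chance as a source. A difference in library preparation or sequencing may also lie behind them and was not tested, as the labels give no batch.

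The lower Schwann or satellite glia-like share in GelNB-CH, -13.3 points, remained under settings that target technical sources. It was -18.6 points with no doublet calls removed, though the fold was 3.30 in place of 4.86 as both shares were larger. With the looser cell filter it was -13.1 points, which argues against the filter as the whole source. Cells were clustered and named anew under each setting, so the class may not hold the same cells. Without doublet removal it may take in cells like cluster 14, which had all 10 glial markers but no name. That setting therefore does not isolate doublet removal, though the direction held. Per otic epithelium-like cell, Schwann or satellite glia-like cells were 6.54-fold more frequent in Matrigel. The fold was 3.1045 with each library clustered and named on its own, where the classes may not hold like clusters. Dilution of both classes by other cells would not account for the lower share. The placement of the reporter gate and the matrix stay open: SOX2 in this class was at 35.4 CPM in GelNB-CH and 23.0 CPM in Matrigel, but in otic epithelium-like cells it was at 12.4 and 20.8 CPM, so these levels give the gate no clear direction.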
